A study of Mus musculus with 6 samples.

How the data were processed

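Total RNA of spleens from 3-week-old Brx haploinsufficient and wild-type C57BL/6 mice was labelled by an indirect dendrimer method from 2 µg RNA and hybridised to printed cDNA clone arrays, per the labels' protocols. Each array held both genotypes, 1 in Cy5 and the other in Cy3, and the labels give 3 replicates with a labelling swap for each. Per the file headers, the slides were quantified with ScanArray Express by an adaptive circle method. The deposited files give, per spot, foreground and local background intensity in both channels with no background subtraction. They also give the percent of a spot's pixels that are saturated; at most 2 spots per array and channel had over 50% saturated pixels, and none was left out for it. The files' log2 ratio of Cy5 over Cy3 was normalised by LOWESS in the scanner software, per the file headers. The deposited flag is a score from 0 to 3 whose meaning the files do not state: spots with flag 3 were bright (median net signal 271 to 1648) and spots with flag 1 dim (7 to 64), so only spots with flag 3 were used. The authors' value table holds log2 ratios that, within 0.02, equal the scanner's log ratio for 92.8% to 98.9% of probes on arrays labelled as haploinsufficient in Cy5, and its opposite for 95% to 96.6% on the swapped arrays. Its scale and direction are thereby haploinsufficient over wild type by the labels, with column medians between -0.0587 and 0.0281 and no further centring. How the authors blanked part of its probes is not given in the sources used here.

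Clone names come from the deposited files. They were updated through the synonyms of a RefSeq gene table (assembly GRCm38.p6, used only for names and for neighbours of Akap13): of 9615 names, 5583 were current symbols, 3704 were updated and 328 were kept as given, 7 of all names reading as calendar days. Clones named EST or with conflicting names (4142) were tested but not named. Coordinates are not printed, since no build is named for the arrays. Clones that share a name were treated as separate probes. Over 2726 random pairs of tested clones with 1 name, brightness correlated with r = 0.22 across clones and the log2 ratio with r = 0.126. For random names the values were -0.00777 and -0.0208. Clones of 1 name thus agreed only weakly, which does not by itself test whether the names are right.

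Foreground medians were corrected with limma 3.58.1 (R 4.3.3) by normexp with offset 50 and normalised within each array by loess, with weight 0 for 388 blank spots, 160 control spots and flagged spots. Ratios were turned to haploinsufficient over wild type by the labels. Probes were tested where the foreground median exceeded the local background median by 2 background SD in either channel on at least 3 of 6 arrays. The 2 arrays of a replicate were averaged, where both had a value, and the mean of the replicates was tested against 0 with lmFit and eBayes, two-sided, for probes with at least 2 replicates, at a Benjamini-Hochberg adjusted p of 0.05. Gene lists (27, fixed before the data were examined, 21 of them with at least 4 measured genes) were tested with camera at a preset correlation of 0.01, using each gene's brightest tested clone. The p-values measure the spread between the replicate values in the fit. Over 3 replicates, the value of replicate 2 is a scan averaged with its own opposite, and lies near 0. It holds no genotype ratio, so the SEs and p-values of that fit do not measure the spread of 3 biological replicates.

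The same-numbered arrays pair by design, since the labels describe each as a swap of the same comparison. Their deviations from the means of the 2 orientations correlated with r = -0.349, -0.587 and -0.217 in replicates 1, 2 and 3. The files were quantified on 4 days in 2 rounds, and the later round held both arrays of replicate 3 alone. A round therefore cannot be told apart from a replicate. Replicates 1 and 3 hold both orientations, while the 2 files of replicate 2 hold 1 scan and so 1 orientation. The single scan behind both files of replicate 2 was found on comparing the arrays. The planned fit was kept, and the planned fit without replicate 2 is given beside it.

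The fit was tested on simulated values for 14947 probes with the spread of replicates 1 and 3. With the effect in all 3 replicates, it recovered 100 of 100 probes changed by a log2 of 1, with 1 false call. With replicate 2 cancelled it recovered 0 of 100 at a log2 of 1 and 0 of 100 at 2, and on replicates 1 and 3 alone 97 and 100 of 100, with 5 false calls. Simulated probes share 1 spread per replicate, so the shifts added to real values and given with the results are the stricter test.

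Named genes follow a rule fixed before the data were examined: every Akap13 clone; up to 12 clones per direction with the same sign on all 6 arrays, past the threshold first, then by fold of at least 1.5 and unadjusted p, then by unadjusted p alone; up to 4 genes with the largest moderated t from each called list and from the erythroid, B cell, T cell, osmotic stress, pancreas, sex-linked and Akap13 neighbour lists; and Nfat5, Xist, Ddx3y and Eif2s3y. One further list that was tested, and that the rule also covers, is not reported here. Other list members named were chosen after their values were seen. Alternatives covered background correction, normalisation within and between arrays, the filter on dim probes, flagged spots, treatment of the 2 arrays of a replicate, dye orientation, the prior, the authors' value table, leaving out each replicate and, for lists, the correlation, the test and the probe per gene. Figures were drawn with matplotlib 3.10.9.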

Results

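The series compared spleens of 3-week-old C57BL/6 Brx haploinsufficient mice with spleens of wild-type mice. Brx is the older name of Akap13, a large protein that anchors protein kinase A. Haploinsufficient and wild-type RNA were hybridised together on 2-colour arrays of printed cDNA clones, so each array measured their ratio directly. By the labels, the 6 arrays are 3 biological replicates, each hybridised with both dye orientations: 3 arrays carried haploinsufficient RNA in Cy5 and 3 carried it in Cy3. An array held 23232 spots in 12 blocks and 22674 different clones, of which 18532 had a gene name. The median spot signal was 498 to 1252 in Cy3, over a median local background of 94 to 160, and 262 to 1176 in Cy5, over a background of 74 to 83. Between 68.8% and 79.8% of clone spots per array lay above background in at least 1 channel, against 8.51% to 11.9% of blank spots. The labels do not say how many animals gave each RNA, and the number of arrays limits the precision.

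The 2 files of replicate 2 held the same scan. Both headers name the same image and the same detector settings, 51.9% of their spots had identical coordinates, and their log2 local background correlated with r = 0.995 in Cy3 and 0.997 in Cy5. Among the other 14 pairs of arrays, the background correlations lay between -0.294 and 0.254. The labels nevertheless give the files opposite dye orientations. Turning the sign of one and averaging therefore cancelled most values: only 188 of 16445 clones, 1.14%, kept an average over 0.1 in size, and the SD of the replicate's log2 ratios over clones was 0.02, against 0.19 in replicate 1 and 0.34 in replicate 3. The direction of this scan is not settled by the labels. As haploinsufficient over wild type, the file labelled as haploinsufficient RNA in Cy5 correlated over clones with r = -0.311 (Spearman -0.036) with the array of replicate 1 of the same label and -0.198 with its swap, and with -0.112 and -0.123 with the arrays of replicate 3. The scan counts as at most 1 replicate, and the average of its 2 files holds no genotype ratio. Over 3 replicates, SEs and p-values still take that average as a value near 0. The tests are given over all 3 replicates, as planned, and the counts, the Akap13 clones, the list calls and the leading genes also over replicates 1 and 3 alone, which rest on 4 separate arrays. Because replicate 2 lay near 0, means over replicates 1 and 3 were 1.5 times (median over clones) those over 3 replicates.

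**Figure D1:**
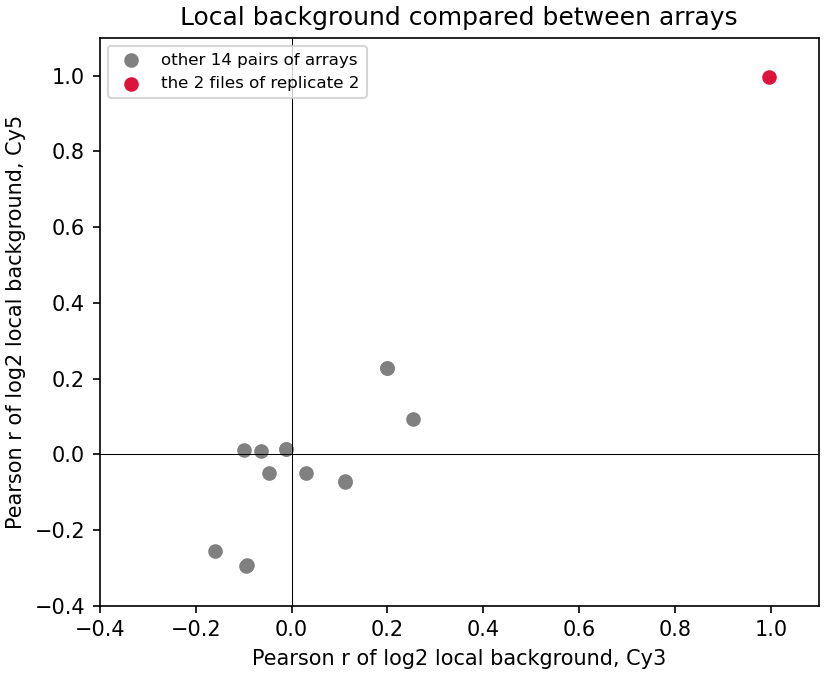
Pearson correlation of log2 local background over 23232 spots, Cy3 on the x axis and Cy5 on the y axis, 1 point per pair of arrays. The pair formed by the files of replicate 2 sits at 0.995 and 0.997, and the other 14 pairs lie between -0.294 and 0.254.

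Akap13 came first, since its level bears on the labels. No Akap13 clone passed the threshold. Of 7 clones with this name, 3 lay above background on all 6 arrays. Log2 ratios of these clones, haploinsufficient over wild type, are given with limma's moderated SE (n = 3 replicates). They were -0.05 ± 0.07 for H4075B02, 0.01 ± 0.06 for H4075D02 and 0.08 ± 0.11 for H4075G09, the brightest. The adjusted limma p-values were 0.822, 0.946 and 0.819. The planned exact sign-flip permutation over the replicates is not reported, since 3 replicates allow no p below 0.25. Over replicates 1 and 3 the values were -0.07 ± 0.12, 0.01 ± 0.12 and 0.12 ± 0.16, and their 95% intervals reached no lower than -0.38, -0.29 and -0.30. A halved level would give -1. The other clones, H4075E02, H4075G02, H4075H02 and H4076D04, were above background on at most 1 array and were not tested. Neither the labels nor the files say which part of Akap13 the disrupted allele lacks or which part each clone covers, so these values do not settle the genotype labels.

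**Figure D2:**
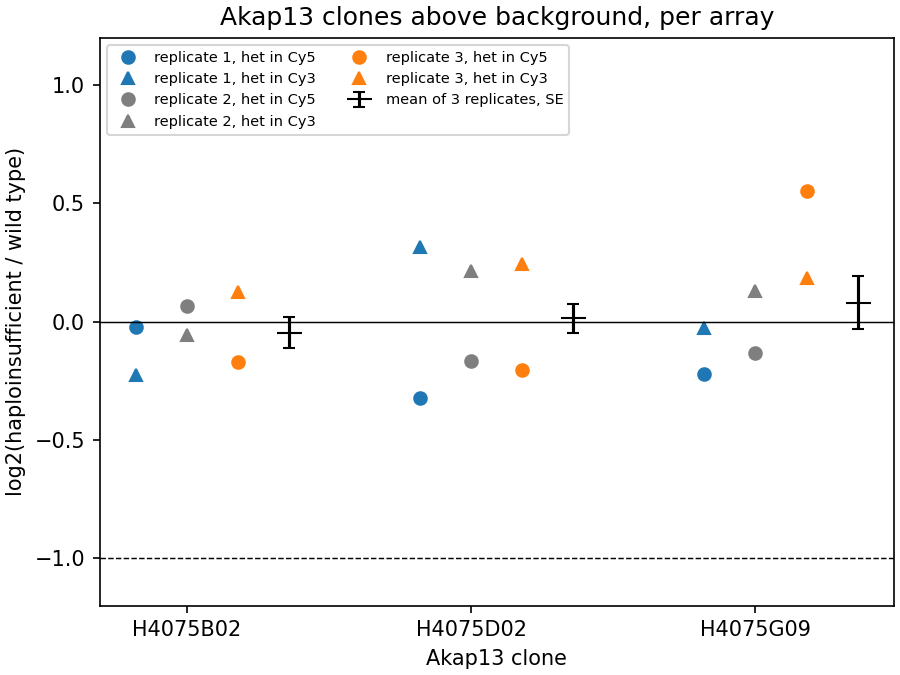
Log2 ratio of haploinsufficient over wild type (y axis) for the 3 Akap13 clones above background (x axis), on each array by replicate and dye orientation, with the mean of 3 replicates and its SE; the dashed line marks -1. All array values lie above -1, and the means are -0.05, 0.01 and 0.08.

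The first comparison asked which genes differed between haploinsufficient and wild-type spleen. None passed the threshold. Over 3 replicates, limma called 0 of 16708 clones at an adjusted p of 0.05, with a smallest adjusted p of 0.766. Under an unadjusted p of 0.05 lay 186 clones, 1.11%, where the chance rate is a share of 0.05. Over replicates 1 and 3 limma called 0 of 15306, with 1073 (7.01%) under an unadjusted p of 0.05 and a smallest adjusted p of 0.681. The count over replicates 1 and 3 bounds only large changes shared by many clones, and the count over 3 replicates not even these. When a 4-fold change was added to replicates 1 and 3 of 200 clones, the fit on these replicates recovered 197. With replicate 2 left near 0 in the fit, 0 were recovered. An added 2-fold change was recovered in 0 of 200 clones by either fit. The 200 clones were changed together, which eases the adjustment over clones. A large change in a few clones could therefore still be missed.

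Genes with the same sign on all 6 arrays were few, because the files of replicate 2 mirror each other: 17 named clones met this, none with a change of at least 1.5-fold, and none passed the threshold. The condition picks clones on which the 2 quantifications of the scan disagree, so replicate 2 adds no genotype ratio for them and the values here are over replicates 1 and 3 (log2, SE). Above 0 lay Clgn, a chaperone of the endoplasmic reticulum, at 0.40 ± 0.13, Rad21, a cohesin subunit, at 0.48 ± 0.12, and BC011248 at 0.29 ± 0.13. With print-tip loess on these replicates, the values were 0.09 for Clgn, 0.42 for Rad21 and 0.13 for BC011248. Below 0 lay Tm9sf2 at -0.31 ± 0.12, Sdccag8 at -0.40 ± 0.12, Tmod3, which caps actin filaments, at -0.38 ± 0.15, and Zfp87 at -0.27 ± 0.13. Rnf216, Lims1, Prep, Commd10, Pdgfc, Tst and Cul4b had values from -0.24 ± 0.12 to -0.16 ± 0.12. Print-tip loess moved Tm9sf2 to -0.20, Tmod3 to -0.25, Commd10 to -0.10 and Cul4b to -0.06. Another was a clone of Nfat5, the transcription factor of the response to osmotic stress; the naming rule stops at 12 clones per direction and leaves out 2 of the 17. This Nfat5 clone, H4075H12, had -0.35 ± 0.13 (adjusted p = 0.7), and over all 3 replicates -0.24 ± 0.10, and was above background on 3 arrays. Over 3 replicates, the brighter Nfat5 clones H4074C10, H4075A12, H4075F12 and H4075G12 had 0.07 ± 0.07, -0.13 ± 0.13, -0.03 ± 0.09 and -0.04 ± 0.06, and H3019B02 was below background. In the 4 arrays of replicates 1 and 3, 777 clones lay above 0 on every array and 815 below, 10.4% of 15306. Independent signs would give 12.5%. The 2 arrays of a replicate were not independent, with r = -0.246 in replicate 1 and -0.13 in replicate 3, so the shares are not directly comparable.

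The second comparison asked whether gene groups shifted together, over 21 gene lists with at least 4 measured genes. Camera called the erythroid list as lower in haploinsufficient spleen (adjusted p = 0.0174). Over 3 replicates, 11 of the 13 measured genes lay below 0, with a median log2 ratio of -0.08 and a mean of -0.15. With an estimated correlation between genes, the adjusted p was 0.905. Fry, which asks whether the genes move one way on balance without comparing them with other genes, gave an adjusted p of 0.575. No single erythroid gene passed the threshold, over all clones or adjusted over the list alone. Over replicates 1 and 3 the median was -0.12 (camera, adjusted p = 0.00327, and 0.974 with an estimated correlation). That correlation is estimated from 2 replicate values per gene, or over 3 replicates from 3 values, 1 of them near 0. With so few values this version of camera can hardly call any list, so it does not decide the question. Without replicate 1, where replicate 3 stood beside values near 0 alone, the median was -0.07 and the call was lost. Reading the scan of replicate 2 as haploinsufficient RNA in Cy5 also ended it (adjusted p = 0.694), and reading it as Cy3 kept it (adjusted p = 0.000559).

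Among erythroid genes, Car1, a carbonic anhydrase of red cells, had -0.60 ± 0.12 (log2, SE, over replicates 1 and 3). It was the dimmest of the 13 genes and lay above background on 5 arrays. The brightest clone of the alpha globin gene Hba-a1 had -0.50 ± 0.12. Alas2, which starts haem synthesis in erythroid cells, had -0.49 ± 0.16, and the blood group gene Kel -0.45 ± 0.12. Rhd had -0.50 ± 0.19, from -0.83 in replicate 1 and -0.16 in replicate 3. The adjusted limma p-values of these genes lay at 0.681 or above. Over all 3 replicates their values, in the order named, were -0.40 ± 0.15, -0.33 ± 0.12, -0.33 ± 0.15, -0.29 ± 0.12 and -0.33 ± 0.18. Below 0 in both replicates were 6 of the 13 genes, 1 was above 0 in both, and 6 went opposite ways, among them the erythroid transcription factor Gata1 and the anion exchanger Slc4a1. Of the 27 Hba-a1 clones with a value in both replicates, 19 lay below 0, and their median was -0.38. By array, the median of the Hba-a1 clones was -1.06 with haploinsufficient RNA in Cy5 and 0.12 on the swap in replicate 1, and -0.44 and -0.36 in replicate 3. In the scan of replicate 2 it was 1.11 or -1.10, depending on which file's label is read. Apart from Hba-a1, the list's genes were measured on plates without Hba-a1 clones, and the median of these 12 genes over replicates 1 and 3 was -0.11.

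**Figure D3:**
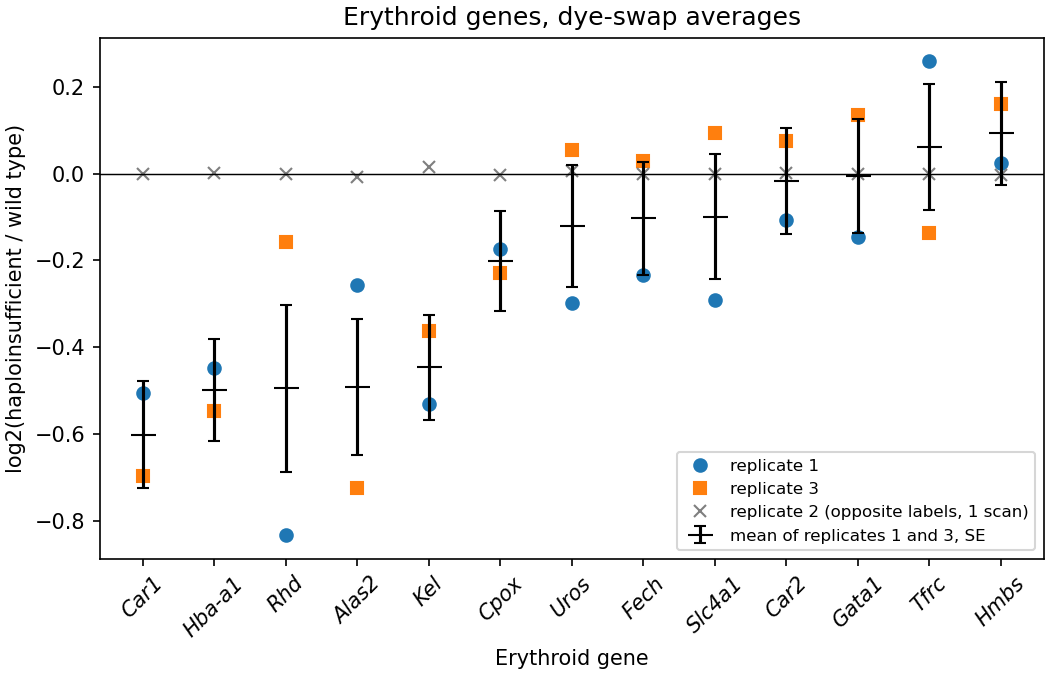
Log2 ratio of haploinsufficient over wild type (y axis) for the 13 erythroid genes (x axis), each replicate as the average of its dye swap, with the mean of replicates 1 and 3 and its SE. Values of replicates 1 and 3 lie below 0 together for 6 genes, and those of replicate 2 lie near 0 for all 13.

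The other 20 lists were not called, over 3 replicates or over replicates 1 and 3, where their adjusted p-values ran from 0.0799 to 0.985. For p38 MAPK genes, 10 of 11 measured genes lay above 0 (median 0.12, camera adjusted p = 0.138), among them Mapkapk2 at 0.34 ± 0.15 and Mapkapk5 at 0.30 ± 0.17 (n = 3 replicates). The median over replicates 1 and 3 was 0.18 (adjusted p = 0.0799), with Mapkapk2 at 0.50 ± 0.15 and Mapkapk5 at 0.45 ± 0.19. Over 3 replicates, the p38 MAPK list had an adjusted p of 0.905 with an estimated correlation and 0.575 with fry. With camera after print-tip loess it was 0.469. Mapk14 had 0.005 ± 0.09 over 3 replicates, from 0.19 in replicate 1 and -0.17 in replicate 3. The genes of protein kinase A and its anchors had a median of 0.03 (adjusted p = 0.956). The osmotic stress and NFAT5 target list, with 6 measured genes, had a median of -0.05 (adjusted p = 0.38). In it the amino acid transporter Slc38a2 had -0.28 ± 0.12, Sgk1 -0.09 ± 0.09, Akr1b3 -0.06 ± 0.08 and Hspa4l 0.07 ± 0.19. Over replicates 1 and 3 the list's median was -0.07 (adjusted p = 0.354) and Slc38a2 had -0.41 ± 0.13. Slc38a2 was measured on a plate that also holds Hba-a1 clones.

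Lymphoid lists held few measured genes. Of 20 B cell genes, 15 had no clone of that name, and of 24 T cell genes 13 had none and 7 more had a clone that could not be tested. The 5 B cell genes had a median of 0.08 (adjusted p = 0.302), with Cd79a, a part of the B cell receptor, at 0.29 ± 0.12, Cd22 at 0.09 ± 0.09, Pou2af1 at 0.08 ± 0.07 and Cd74 at 0.06 ± 0.07. The B cell median over replicates 1 and 3 was 0.11 (adjusted p = 0.345) and Cd79a had 0.44 ± 0.13. The 4 T cell genes had a median of -0.03 (adjusted p = 0.732), with Cd2 at -0.14 ± 0.10, Tcf7 at -0.09 ± 0.08, Cd247 at 0.05 ± 0.06 and Lck at 0.04 ± 0.08, and over replicates 1 and 3 a median of -0.04 (adjusted p = 0.73). Medians were 0.11 for cytokines and receptors of lymphocytes (adjusted p = 0.236), 0.06 for MHC class II (adjusted p = 0.732) and 0.004 for immunoglobulin and plasma cell genes (adjusted p = 0.732), whose mean was -0.005. Neutrophil and granulocyte precursor genes had a median of -0.01 and a mean of 0.03 (adjusted p = 0.956), and red pulp macrophage genes a median of -0.02 and a mean of 0.02 (adjusted p = 0.956).

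Lists of general cell functions were not called either. Oxidative phosphorylation genes had a median of 0.07 (adjusted p = 0.219), with 31 of 44 above 0. By replicate, their median was -0.04 in replicate 1 and 0.22 in replicate 3. Cell cycle genes also went opposite ways, with -0.06 in replicate 1 and 0.17 in replicate 3. The medians were 0.02 for cytosolic ribosomal proteins (adjusted p = 0.81), 0.02 for cell cycle (adjusted p = 0.956) and 0.04 for interferon response (adjusted p = 0.732). They were -0.09 for glucocorticoid response (adjusted p = 0.341), -0.01 for nuclear receptors (adjusted p = 0.732) and 0.06 for stroma and endothelium (adjusted p = 0.732). Immediate early and dissociation stress had 0.04 (adjusted p = 0.971). Without replicate 3, cell cycle was called as lower, at -0.04, but that fit held only replicate 1 beside the values near 0 of replicate 2. Genes next to Akap13 on chromosome 7 had a median of 0.01 over 23 genes (adjusted p = 0.956). Over replicates 1 and 3 the median was 0.01 (adjusted p = 0.941). In that list, over 3 replicates, Isg20 had 0.40 ± 0.21, Crtc3 0.28 ± 0.16, Blm 0.18 ± 0.09 and Pde8a -0.22 ± 0.12. Adjusted over the list alone, 0 genes of any of the 21 lists passed.

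Sex-linked (3 measured genes), dendritic cell (3), megakaryocyte and platelet (3), pancreas (1), adipocyte (1) and NK and cytotoxic (1) genes were too few to test as lists. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d, by their brightest clones, had -0.05 ± 0.07, -0.04 ± 0.06 and -0.001 ± 0.11, and 0 clones carried the name Xist. The other tested clones of Ddx3y lay between -0.04 and 0.02 and those of Eif2s3y between -0.02 and 0.15. The only pancreas gene measured, the carboxypeptidase Cpa1, had 0.11 ± 0.09.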

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

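Control spots, which enter no comparison, lay above background more often than blank spots on every array: 21.2% on the array with the lowest share and 56.9% on the highest, against at most 11.9% of blank spots. The files do not say what was printed there, and no explanation was tested.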

How the results depend on the processing

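Under all alternatives, with no exception, limma called 0 clones, with unadjusted counts from 0 (intensity trend and robust prior) to 2174 (arrays with haploinsufficient RNA in Cy3 only). With dye term and replicate block the values were 0 clones (616 unadjusted), 1 list and 0.08 for the brightest Akap13 clone, so the block changed no call. That clone stayed within 1 SD of its value, from -0.06 without replicate 3 to 0.18 without replicate 1. Fits without replicate 1 or without replicate 3 held a single genotype ratio per clone, beside the values near 0 of replicate 2. The number of called lists, 1, became 0 with probes above background on all 6 arrays, with only the arrays of haploinsufficient RNA in Cy5, with the trend and robust prior, with an estimated correlation and with fry; leaving out a replicate gave 0 (replicate 1) to 2 (replicate 3, with cell cycle added as lower). The erythroid median, -0.079, lost its call at -0.069 with probes above background on all arrays (adjusted p = 0.089), -0.032 with Cy5 only (0.846), -0.079 with the trend and robust prior (0.0941), an estimated correlation (0.905) or fry (0.575), and ranged from -0.13 to -0.068 without 1 replicate. It kept its call at -0.24 with haploinsufficient RNA in Cy3 only (0.0398), -0.16 with the mean of all probes of a gene (0.000558) and -0.14 with print-tip loess (0.00234). Fits on 1 orientation cannot part dye from genotype, and each takes 1 file of replicate 2. On that file the erythroid median was 0.23 for the Cy5 fit and -0.20 for the Cy3 fit. In replicates 1 and 3 it was -0.48 and -0.29 with haploinsufficient RNA in Cy5, and -0.12 and -0.17 in Cy3. Alternatives chosen after seeing the data read the scan of replicate 2 as haploinsufficient in Cy5 (0 lists, erythroid -0.036, adjusted p = 0.694) or in Cy3 (2 lists, p38 MAPK added), left out the plates with 2 or more Hba-a1 clones, used 4 arrays, mean pixels, or print-tip loess on replicates 1 and 3. The other 56 named clones gave 1329 values, 78 with the sign turned, 65 moved by 1 SD or more and 0 past the threshold. The cause of these differences was not tested. The estimated correlation used 3 replicate values per gene, 1 of them near 0, so it could hardly call any list. Aquantile leaves log ratios as they are, so it tests nothing here. Dim probes are limited by signal over background.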

Other observations

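Of the tests below, those of the background, of the erythroid medians per array and over dye swaps, of erythroid members by plate and by replicate, and of brightness were chosen only after the result was seen.

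Clones in wells next to an Hba-a1 clone shifted with it. On the 12 plates that hold Hba-a1 clones, 113 clones in adjoining wells lay -0.12 (log2, median, over replicates 1 and 3) from the other 934 non-globin clones of these plates matched on brightness (permutation of wells within plates, one-sided p = 0.0001, the smallest that 10000 draws can give). The permutation moved wells singly, while adjoining wells lie in clusters around Hba-a1 wells, so this p-value may be too small. Carry-over of globin cDNA between wells may be a cause, and clones of globin under another name would give the same value. The comparison took no account of the blocks of the slide, whose medians still differed after loess, and was not repeated with print-tip loess. A separate comparison took whole plates. On the 4 plates with at least 2 Hba-a1 clones, non-globin clones lay -0.084 from clones of other plates in the same brightness bin. This lay outside the -0.056 to 0.073 that held 95% of 10000 draws of as many plates. It argues against brightness as the whole cause of the shift of these 4 plates. It does not bear on the difference between adjoining and other wells, which was itself matched on brightness. No biological explanation was tested.

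The files of replicate 2 behave like a single slide quantified again: the lower of their background correlations was 0.995, and the highest of any other pair 0.254. A consequence shows in the splits of the 6 arrays into 3 and 3. The real split called 0 clones and the highest of the others 21. The 4 splits that keep both files together gave 1300 to 1943 clones under an unadjusted p of 0.05, and those that part them at most 213 (206 in the real split), which points to this structure of the samples. The 10 splits, 4 of which part all 3 pairs, are too few for a share under 0.05. No biological explanation was tested.

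The lower erythroid list stays open. Its median on the array with haploinsufficient RNA in Cy5 and on its swap was -0.48 ± 0.12 and -0.12 ± 0.13 (SE of the median over 13 genes) in replicate 1, and -0.29 ± 0.14 and -0.17 ± 0.16 in replicate 3, so it lay below 0 by more than its error on 3 of 4 arrays, and effects of single arrays stay open. A dye effect that repeats between arrays would cancel in the dye-swap averages, whose median was -0.12 ± 0.09. Carry-over of globin would leave the 12 members on plates without Hba-a1 clones near 0, and their median was -0.11 ± 0.09. Both medians lie little further from 0 than their error, which takes genes on the same arrays as independent. Neither explanation is decided by these values. Fewer erythroid cells or transcripts would lower most members in both replicates: 6 of 13 were, where independent signs would give 3.25, which leaves this explanation open. The real split called 1 list and the highest of the others 2; the 10 splits are too few for a share under 0.05.

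Ratios also differed with dye orientation and between blocks of the slide. After loess, the block medians of log2 Cy5 over Cy3 ran from -0.56 to 0.21 on the swapped array of replicate 1 and from -0.31 to 0.36 on the array of replicate 3 with haploinsufficient RNA in Cy5. As haploinsufficient over wild type, the 2 arrays of a replicate correlated with r = -0.246 across clones in replicate 1 and -0.13 in replicate 3. Arrays of the same orientation from these replicates correlated with r = 0.213 and 0.307, and their dye-swap averages with r = 0.25. A dye term over these 4 arrays passed the threshold for 0 of 15306 clones in limma, with 2060 under an unadjusted p of 0.05.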
